A study of Mus musculus with 6 samples.

How the data were processed

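RNA-seq was done on primary airway smooth muscle cells (ASMC) from the lungs of wild-type mice. Cells of 3 samples had been grown for 5 days in transwell plates together with mouse airway epithelial cells, and cells of 3 samples had been grown without them. A transwell plate keeps both cell types apart on a porous membrane that lets dissolved molecules through. Per the labels, the smooth muscle cells were lysed in Trizol and total RNA was extracted. Reads were aligned with HISAT, per the labels' protocols, to the mouse genome build mm10, per the submitters' processing notes. The counting program, the annotation release, the library kit, its strandedness and the program versions are not given in the sources used here. Samples were grouped by the treatment in their labels. The columns of the deposited tables number the co-culture libraries 1 to 3 and the control libraries 4 to 6, whereas the labels number the controls from 1 again, so control columns were assigned to their group and not to single labelled samples. Control libraries are named here by their column number. Nothing in the sources says whether the 3 samples of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

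A table of 17023 genes and a table of 58236 RefSeq transcripts were used. Both hold estimated counts, FPKM and TPM as deposited by the authors. Control columns were used at the level of their group, and of these only the counts, on which the tests rest, were taken, so 12 deposited columns of control FPKM and TPM were not used here. FPKM and TPM of all libraries were instead computed from the counts and the gene lengths implied by the deposited co-culture counts and FPKM. For co-culture libraries, computed and deposited values differed by a median of 0.0034 (FPKM) and 0.0107 (TPM) on the log2 scale. The deposited counts are estimated counts that need not be whole. The deposited FPKM values are the authors' counts scaled to gene length and library size, per the file headers. The deposited TPM values are scaled so that each co-culture library sums to 1000000, per the file headers and the sums found. Gene counts equalled the sums over each gene's transcripts, with 0 genes differing by more than 1 read in any library. Gene IDs were matched to a RefSeq gene table of GRCm38.p6, the assembly that mm10 denotes, and 16975 of them (99.7%) were found. Coordinates come from that table, are 1-based and refer to that assembly. Of all genes, 16878 were protein coding in that table.

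Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3). Genes were kept by filterByExpr, library sizes were scaled by TMM factors, and edgeR's quasi-likelihood test (glmQLFit, glmQLFTest) compared co-culture with control with no covariate. P-values were two-sided and were adjusted by the Benjamini-Hochberg method. A gene was called, and is said to have risen or fallen, at an adjusted p under 0.05. Fold changes are log2(co-culture over control). Their standard error (SE) is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Normalised levels of genes are counts divided by the TMM-scaled library size and multiplied by 1000000 (CPM), given as mean ± SD over 3 libraries. For CPM of transcripts the library total was used without a TMM factor, so they are not on the scale of the gene values. Transcripts were tested in the same way as genes. Changed isoform use was tested with edgeR's diffSpliceDGE, which compares each transcript with the other transcripts of its gene and gives a Simes p per gene. Estimated transcript counts divide reads among transcripts that overlap almost completely, so single transcripts carry more uncertainty than genes do.

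The test, the samples in it, the gene lists, the rule for named genes and most of the alternatives were fixed before the data were examined. The lists were cell cycle and mitosis, DNA replication, smooth muscle contractile, extracellular matrix, matrix remodelling proteases and inhibitors, TGF-beta response, chemokines and cytokines, NF-kB response, interferon response, growth factors and receptors, Wnt signalling, hedgehog signalling, Notch signalling, hypoxia and glycolysis, cholesterol biosynthesis, ATF4 and unfolded protein response, p53 targets and senescence, NRF2 and oxidative stress, immediate early genes, retinoid and aryl hydrocarbon response, prostanoid and lipid mediators, markers of airway epithelial cells, leukocytes, endothelial cells, fibroblasts, mesothelial cells and pericytes, and mitochondrially encoded transcripts. Members of that last list, as well as Cdh1, Scgb1a1 and Sftpc, were not analysed here. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 27 lists with the Benjamini-Hochberg method. Camera with an estimated correlation and fry were run beside it. Camera compares a list with all other genes. Fry asks whether the members of a list move, on balance, one way, and compares them with no other genes.

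Named genes followed 3 rules. The first took, among called genes with a mean of at least 5 CPM and no overlap between the groups, the 10 with the largest rise and the 10 with the largest fall. The second took from each list the 2 members with the smallest adjusted p in each direction. The third fixed Mki67, Ccnd1, Pcna, Acta2, Myh11, Tagln, Cnn1, Col1a1, Epcam and Cdh1 whatever their result. Transcripts were named only for the 5 genes with the smallest adjusted p for isoform use. Some genes that these rules select are not reported here. Genes outside these rules are said to be chosen after their values were seen.

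Total estimated counts per library lay between 17496056 and 18496623, a range too narrow for depth to separate the groups. The common dispersion was 0.0225 for genes and 0.427 for transcripts. The code was tested on counts simulated from the means, trended dispersions and library sizes found, with 200 changed genes or transcripts. Changed genes and transcripts were drawn only from those above a minimum mean count, so recovery at low counts was not measured. For isoform use, the transcript with the highest mean of each chosen gene was changed. In the gene simulation 34.3% of genes changed 1.5-fold, 91.04% of those changed 2-fold and 100% of those changed 4-fold were recovered, and 8 of 158 calls were wrong. In the transcript simulation the shares were 1.54%, 13.6% and 50.8%, with 0 wrong among 42 calls. For isoform use, 10.5% of 200 genes changed 4-fold were recovered, with 1 wrong among 22 calls. In 20 simulations that raised the NF-kB response list 1.3-fold, camera found it in 20. It called 0 in 500 tests of other lists that share no member with it. Genes were simulated independently, so this does not measure false calls where members vary together. The correlation estimated for the interferon response list, for example, was 0.753.

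Alternatives were DESeq2's size factors in edgeR, DESeq2's Wald test (DESeq2 1.42.0), no filter on low counts, a stricter filter (at least 1 CPM in all libraries of a group and a mean count of at least 10), a minimum change of 2-fold, limma with a trend on log2(FPKM + 1), log2(FPKM + 0.1), log2(TPM + 1) and log2(TPM + 0.1), all on computed values, and leaving out each library in turn. Fold changes on these log2(value + pseudocount) scales understate the change of low genes. A correction of each library for gene length (lowess with a span of 0.3), limma's voom with sample quality weights, camera on FPKM and TPM, and the computed FPKM and TPM themselves were added after seeing the data. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used to read the tables.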

Results

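Airway smooth muscle cells form the contractile layer around the airways. RNA levels in mouse ASMC were measured after 5 days of transwell culture, in 3 samples that shared the plate with airway epithelial cells and in 3 control samples that did not. Total estimated counts were 18496623, 17496056 and 18029916 in co-culture libraries 1 to 3 and 18288954, 17997380 and 18410934 in control libraries 4 to 6. The most abundant gene, the translation factor Eef1a1, took 1.04% to 1.37% of the counts, and the 10 most abundant genes took 5.04% to 6.04%. Replicate libraries were compared over genes by a chi-square per degree of freedom, where 1 would mean counting noise alone. It was 4.12 to 6.78 among co-culture libraries and 3.29 between control libraries 5 and 6. Control library 4 stood apart from the other controls, at 96.6 against library 5 and 105 against library 6, whereas values between the groups ranged from 48.004 to 128. No library was dropped, and many of the results that moved without control library 4 are given both ways. Values are normalised counts (CPM, mean ± SD, n = 3 per group) and log2 fold changes with standard errors (SE).

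The series asked what lies behind a smooth muscle proliferation phenotype, and its single comparison was co-cultured against separately cultured ASMC. In co-culture, 22 of 25 NF-kB response genes rose (camera adjusted p = 2.11e-14 with the preset correlation and 0.317 with an estimated correlation). Among them C3, the central complement protein, rose from 177 ± 35.1 to 1178 ± 111 CPM, and Ptx3, a secreted pattern-recognition protein, rose from 9.46 ± 2.198 to 134 ± 26.6 CPM. Axin2, a feedback inhibitor and transcriptional target of Wnt signalling, rose from 2.48 ± 0.557 to 31.3 ± 3.12 CPM. The ligand-activated transcription factor Ahr rose from 14.6 ± 1.79 to 147 ± 7.73 CPM. Eln (elastin) fell from 317 ± 36.7 to 87.9 ± 7.58 CPM. It was among 14 of 31 extracellular matrix genes that fell, while 2 rose and 15 did not pass. The matrix list gave a camera adjusted p of 0.00104 with the preset correlation and 0.646 with an estimated correlation. With an estimated correlation 0 lists passed. The proliferation marker Mki67 did not pass the test, at 158 ± 22.7 CPM in co-culture and 172 ± 9.46 CPM in controls.

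Of 12936 genes tested, 1333 rose and 1330 fell, together 20.6%, by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. At least 2-fold changes were seen in 342 genes that rose and 323 that fell. All called genes had groups that did not overlap, as had 42.9% of all genes tested, where chance gives 10%. Genes that rose were 69.5% of the calls with log2(FPKM + 1), 68.7% with log2(FPKM + 0.1), 68.3% with log2(TPM + 1) and 66.9% with log2(TPM + 0.1). These alternatives change the test together with the scaling, and computed FPKM and TPM carry no TMM factors. Those factors were 1.0388, 1.0368 and 1.0379 in co-culture libraries 1 to 3 and 0.8855, 1.0098 and 1.0005 in control libraries 4 to 6. On the FPKM scales, leaving them out raises co-culture levels relative to controls. DESeq2's size factors in edgeR gave 53.01%. They also scale between libraries, as TMM does, so that share cannot separate the part of the scaling from that of the test. The median log2 fold change of all genes was -0.041 with edgeR, 0.058 and 0.071 on the FPKM scales and 0.137 and 0.155 on the TPM scales with pseudocounts of 1 and 0.1. Counts were 469 higher and 232 lower with log2(TPM + 0.1) and 2201 and 2488 with quality weights. Leaving out control library 4 gave 2445 higher and 2598 lower, and 2644 of the 2663 calls were shared. They were 668 and 615 without co-culture library 1, 705 and 635 without library 2, 612 and 598 without library 3, 829 and 774 without control library 5, and 903 and 761 without control library 6.

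**Figure D1:**
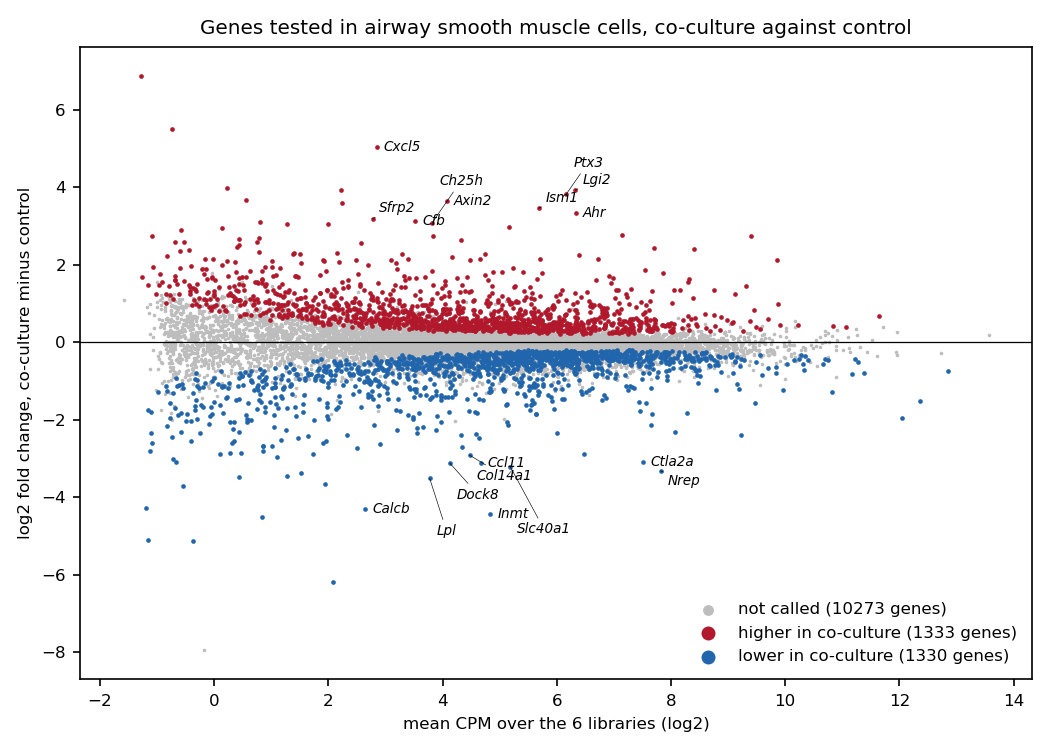
Log2 fold change (co-culture minus control) of each tested gene against its mean level over the 6 libraries (log2 CPM). Red points are the 1333 genes that rose, blue points the 1330 that fell and grey points the genes that did not pass, and the named genes with the largest changes are marked.

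The largest rise among named genes was that of Cxcl5, a neutrophil-attracting chemokine (gene ID 20311, chromosome 5, 90759298 to 90761625), from 0.413 ± 0.0951 to 13.97 ± 2.28 CPM, a log2 fold change of 5.05 ± 0.22 (SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 6.84e-05). Lgi2, a secreted leucine-rich repeat protein (gene ID 246316, chromosome 5, 52533517 to 52566306), rose from 9.896 ± 0.759 to 150.4 ± 7.4 CPM (3.92 ± 0.09, edgeR adjusted p = 1.45e-05). Ptx3 (gene ID 19288, chromosome 3, 66219887 to 66225806) rose by 3.83 ± 0.21 and Axin2 (gene ID 12006, chromosome 11, 108917828 to 108950783) by 3.65 ± 0.17. Ahr (gene ID 11622, chromosome 12, 35497979 to 35534989) rose by 3.33 ± 0.11. Ism1, a secreted protein, rose by 3.46, the Wnt modulator Sfrp2 by 3.19, the complement protease precursor Cfb by 3.13, and Ch25h, which makes 25-hydroxycholesterol, by 3.09. Serpina3f, a serine protease inhibitor, rose by 2.98, but close paralogs lie beside it on chromosome 12 and may share reads, so its value is uncertain. The largest fall was that of Inmt, an N-methyltransferase (gene ID 21743, chromosome 6, 55170627 to 55174990), from 54.7 ± 23.6 to 2.49 ± 0.372 CPM (-4.45 ± 0.36, edgeR adjusted p = 5.57e-04). Calcb, a calcitonin gene-related peptide, fell by 4.31, lipoprotein lipase (Lpl) by 3.52, the iron exporter Slc40a1 by 3.22, Dock8, a guanine nucleotide exchange factor, by 3.13, and the eosinophil-attracting chemokine Ccl11 by 3.12. Nrep fell from 410.3 ± 86.1 to 40.98 ± 1.67 CPM, and Col14a1, a fibril-associated collagen, from 39.2 ± 7.55 to 5.19 ± 0.715 CPM. Control library 4 lay well above controls 5 and 6 for Inmt (80.4 CPM against 49.4 and 34.2), Calcb (18.35 against 9.91 and 7.44) and Ccl11 (69.9 against 36.3 and 30.7). With a library left out, their smallest changes were -4.062, -3.864 and -2.675. For Slc40a1, Dock8 and Col14a1 control library 4 was the lowest control. Ctla2a fell by 3.11, and control library 4, at 644 CPM against 168 and 172 in controls 5 and 6, set part of that size: its change was -2.16 without that library. The Ctla2a call was lost without co-culture library 1, 2 or 3 (edgeR adjusted p = 0.0544, 0.056 and 0.0575), with adjusted p from 1.09e-10 to 0.0575 over all alternatives.

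**Figure D2:**
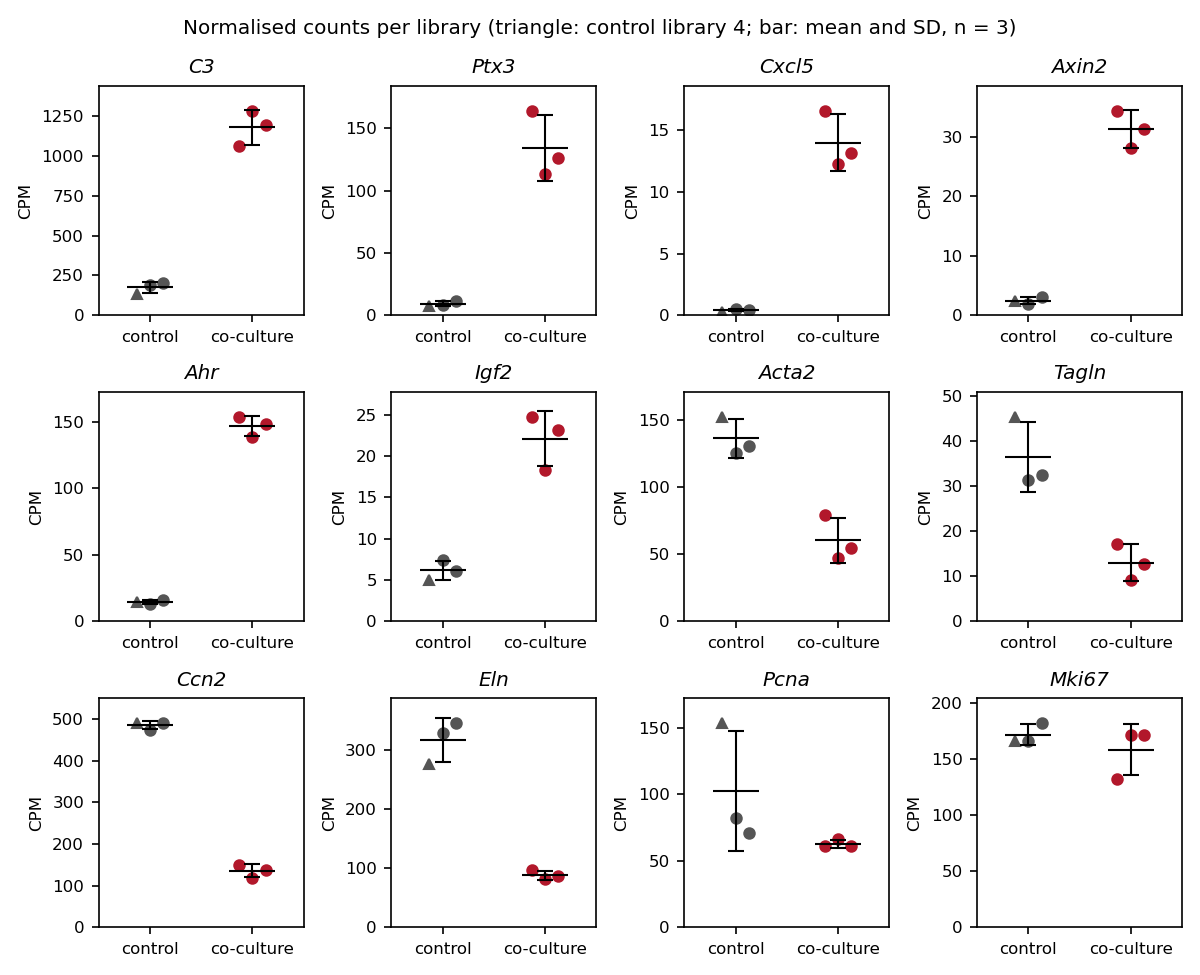
Normalised counts (CPM) of 12 genes in each library, with the mean and SD of the 3 control and the 3 co-culture libraries as bars; triangles are control library 4. C3, Ptx3, Cxcl5, Axin2, Ahr and Igf2 were higher in all co-culture libraries, Acta2, Tagln, Ccn2 and Eln were lower, and Pcna and Mki67 did not pass the test.

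Genes of cell division were either lower in co-culture or did not pass, and 0 members of the cell cycle or DNA replication lists rose. Mki67 changed by -0.12 ± 0.11 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.506), with values from -0.18 to 0.07 over the alternatives: its sign turned with log2(TPM + 1), at 0.064, and log2(TPM + 0.1), at 0.067, and it was 0.000 without co-culture library 1. The G1 cyclin Ccnd1 fell from 579 ± 9.82 to 464 ± 39.5 CPM, a change of -0.32 ± 0.09 (edgeR adjusted p = 0.0429). The Ccnd1 call was lost when any library other than control library 4 was left out (edgeR adjusted p = 0.147, 0.0857 and 0.123 without co-culture libraries 1 to 3, and 0.115 and 0.116 without control libraries 5 and 6), with adjusted p from 0.00303 to 0.822 over all alternatives. Pcna, the replication clamp, was at 62.7 ± 3.05 CPM in co-culture and 102.5 ± 44.95 CPM in controls (-0.71 ± 0.28, edgeR adjusted p = 0.122), with 154 CPM in control library 4 against 82.5 and 70.98 in the other controls. Pcna fell by 0.29 without control library 4 (edgeR adjusted p = 0.00641, and 0.00641 to 0.275 over all alternatives). Of the 30 cell cycle and mitosis genes, 6 fell and 24 did not pass (6 lower adjusted over the list alone), with a median of -0.29 and a camera adjusted p of 0.00102. The list gave adjusted p = 0.646 with an estimated correlation and values from 1.29e-04 to 0.0536 under its other alternatives, the highest with fry. Cyclin E2 (Ccne2) fell by 1.27 ± 0.28 and the spindle midzone protein Prc1 by 0.43 ± 0.096, but both calls were lost without co-culture library 1, 2 or 3 (edgeR adjusted p = 0.0849, 0.0629 and 0.0774 for Ccne2 and 0.0917, 0.0652 and 0.0896 for Prc1). Over all alternatives the adjusted p ran from 4.31e-04 to 0.0849 for Ccne2 and from 0.00134 to 0.675 for Prc1. Of the 30 DNA replication genes, 10 fell and 20 did not pass (13 lower adjusted over the list alone), with a median of -0.44 and a camera adjusted p of 5.17e-05. That list gave adjusted p = 0.646 with an estimated correlation and values from 8.25e-06 to 0.0338 under its other alternatives. The helicase subunit Mcm5 fell by 0.73 ± 0.102 and the ribonucleotide reductase subunit Rrm2 by 0.65 ± 0.096. With control library 4 left out, the 2 lists had 12 and 16 lower members and medians of -0.20 and -0.27. Cell cycle members called lower numbered 0, 1 and 0 without co-culture libraries 1, 2 and 3 and 2 and 3 without control libraries 5 and 6, and DNA replication members numbered 3, 5, 4, 2 and 7.

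Contractile genes moved both ways. Acta2 (smooth muscle actin; gene ID 11475, chromosome 19, 34240336 to 34255585) fell from 136 ± 14.4 to 60.3 ± 16.6 CPM, a change of -1.18 ± 0.19 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00788). The actin-binding protein Tagln fell by 1.48 ± 0.25 and the muscarinic receptor Chrm3 by 1.38 ± 0.16. Calponin (Cnn1), at 0.43 ± 0.116 CPM in co-culture and 0.904 ± 0.153 CPM in controls, fell by 1.07 ± 0.295, and was called with all libraries and without control library 4 but not without any other library (edgeR adjusted p = 0.139, 0.0696 and 0.143 without co-culture libraries 1 to 3, and 0.126 and 0.119 without control libraries 5 and 6; 0.00868 to 0.234 over all alternatives). The smooth muscle myosin Myh11 was low in both groups, at 0.892 ± 0.0677 and 1.25 ± 0.492 CPM, and did not pass (-0.496 ± 0.331, edgeR adjusted p = 0.329), but was called without control library 4 (-0.78, edgeR adjusted p = 0.0424; 0.0334 to 0.838 over all alternatives). Pgm5, a cell adhesion protein, fell by 0.93, while the caveolar protein Cav1 rose by 0.92 ± 0.078. Of 24 contractile members tested, 3 rose, 8 fell and 13 did not pass (6 and 9 adjusted over the list alone), and the list did not pass (median -0.19, camera adjusted p = 0.48); fry put its sign upward without passing. Leaving out control library 4 gave 5 members that rose and 11 that fell, against 5 that fell without co-culture library 1 or 2 or control library 6.

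Most of the extracellular matrix genes that passed fell, 14 against 2 that rose. Eln fell by 1.85 ± 0.11 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.07e-04) and Col14a1 by 2.92 ± 0.18, while Postn (periostin) rose by 0.56 ± 0.129 and Fbln1 (fibulin 1) by 0.30 ± 0.069. The Postn call was lost without co-culture libraries 1 and 3 and control library 5 (edgeR adjusted p = 0.0973, 0.0965 and 0.0841), and that of Fbln1 without co-culture libraries 1, 2 and 3 and control library 6 (0.0782, 0.0968, 0.0964 and 0.0697). Over all alternatives the adjusted p ran from 0.00149 to 0.0973 for Postn and from 0.00343 to 0.357 for Fbln1. The collagen I chain Col1a1 was at 3503 ± 221 CPM in co-culture and 4433 ± 816 CPM in controls and did not pass (-0.34 ± 0.16, edgeR adjusted p = 0.188), but fell by 0.485 without control library 4 (edgeR adjusted p = 2.00e-04, and 2.00e-04 to 0.861 over all alternatives). Of 31 matrix members, 2 rose, 14 fell and 15 did not pass (5 and 17 adjusted over the list alone; median -0.37, camera adjusted p = 0.00104). The list gave adjusted p = 0.646 with an estimated correlation and values from 9.99e-06 to 0.0109 under its other alternatives. Of 30 matrix remodelling proteases and inhibitors, 5 rose, 12 fell and 13 did not pass (6 and 16 adjusted over the list alone; median -0.33, camera adjusted p = 0.0277). That list gave adjusted p = 0.639 with an estimated correlation, 0.0606 without control library 5, and values from 0.00343 to 0.0606 under its other alternatives. The metalloprotease Adam12 fell by 1.19 ± 0.093, whereas the collagenase Mmp8 rose by 2.13 ± 0.15 and Mmp23 by 0.445. Leaving out control library 4 gave 8 matrix members that rose and 22 that fell, and 7 and 18 remodelling members. Matrix members that rose numbered 0, 1 and 0 without co-culture libraries 1, 2 and 3 and 1 without control library 5 or 6, and remodelling members that rose numbered 3, 2, 2, 3 and 2 without these libraries. Matrix members that fell numbered 8 without co-culture library 2 or 3 or control library 5 or 6. Of 32 TGF-beta response genes, 5 rose, 11 fell and 16 did not pass (6 and 16 adjusted over the list alone; median -0.22). This list missed the threshold (camera adjusted p = 0.0637) but passed it in 7 of its 14 alternatives other than the estimated correlation, where adjusted p = 0.646. These included fry (0.0076), log2(FPKM + 1) (0.0238), log2(TPM + 1) (0.0321) and leaving out control library 4 (0.0168) or co-culture library 3 (0.0383). Values ran from 0.0076 to 0.109 over the 14 alternatives. TGF-beta members that rose numbered 3 without each co-culture library. Ccn2 (connective tissue growth factor) fell from 485 ± 10.1 to 135.5 ± 15.6 CPM, and the activin antagonist Fst rose by 1.202 ± 0.068.

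NF-kB response genes were higher nearly throughout. Of 25 members, 22 rose, 0 fell and 3 did not pass (22 higher adjusted over the list alone), with a median of 0.83 and a camera adjusted p of 2.11e-14. The list gave adjusted p = 0.317 with an estimated correlation and values from 5.69e-17 to 8.75e-04 under its other alternatives. C3 (gene ID 12266, chromosome 17, 57203967 to 57228136) rose by 2.74 ± 0.17 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.19e-04). Chemokines and cytokines went both ways: of 23 members, 5 rose, 4 fell and 14 did not pass (5 and 5 adjusted over the list alone). Their median of -0.09 and their mean of 0.12 differed in sign, the test pointed upward, and the list did not pass (camera adjusted p = 0.48). The median also turned to 0.13 without control library 4, and 2 members fell without co-culture library 1. Cxcl1, another neutrophil chemokine, rose by 2.55 ± 0.19 with Cxcl5, whereas Cxcl12, which acts through Cxcr4, fell from 1115 ± 27.2 to 715 ± 24.6 CPM along with Ccl11. Of 35 interferon response genes, 4 rose and 31 did not pass (3 higher adjusted over the list alone; median 0.46, camera adjusted p = 0.00847). The interferon list gave adjusted p = 0.765 with an estimated correlation. Its call rested on co-culture library 1: without it the median was -0.03 (camera adjusted p = 0.36), and the call was also lost without control library 5 (0.0627, median 0.32) or 6 (0.0691), with values from 8.16e-05 to 0.36 over its alternatives other than the estimated correlation. Mean log2 CPM of the interferon list was 5.25 in co-culture library 1, 4.07 and 4.28 in the others, and 4.59, 3.87 and 3.91 in control libraries 4, 5 and 6. The transcription factor Irf1 rose by 0.72 ± 0.066 and the guanylate-binding protein Gbp5 by 1.42 ± 0.24. Interferon members that rose numbered 16 without control library 4. Leukocyte markers summed to 109 ± 7.01 CPM in co-culture and 156 ± 35.3 CPM in controls.

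Wnt signalling genes were higher in most called cases. Of 24 members, 13 rose, 5 fell and 6 did not pass (15 and 5 adjusted over the list alone; median 0.89, camera adjusted p = 3.01e-05). The list gave adjusted p = 0.442 with an estimated correlation and values from 1.28e-07 to 0.00127 under its other alternatives. Besides Axin2, the Wnt inhibitor Apcdd1 rose from 9.09 ± 0.0798 to 44.3 ± 1.85 CPM, while Dkk3 fell from 547 ± 16.4 to 362 ± 24.5 CPM and the R-spondin receptor Lgr6 fell by 0.72 ± 0.13. The Lgr6 call was lost without co-culture library 1 or 2 (edgeR adjusted p = 0.0545 and 0.056; 1.81e-04 to 0.473 over all alternatives). Members that fell numbered 2, 1 and 2 without co-culture libraries 1, 2 and 3. Growth factors and receptors did not pass as a list (39 members, 10 rose, 8 fell and 21 did not pass; 10 and 10 adjusted over the list alone; median 0.06, camera adjusted p = 0.48). Igf2, a growth factor of the insulin family, rose by 1.84 ± 0.18 and the lymphatic growth factor Vegfc by 1.07 ± 0.104, whereas the IGF-binding protein Igfbp5 fell from 449 ± 63.7 to 89.97 ± 7.56 CPM and the EGF receptor ligand Hbegf fell by 1.204 ± 0.105. The growth factor median turned to -0.01 without control library 4. Of 13 hedgehog genes, 4 rose, 3 fell and 6 did not pass (5 and 3 adjusted over the list alone), with a median of 0.02, a mean of -0.04 and an upward test (camera adjusted p = 0.505). The co-receptor Cdon rose by 1.11 ± 0.13 and the transcription factor Foxf2 by 0.67. The median turned to -0.05 without control library 4 and to -0.03 without co-culture library 2. Hedgehog members that rose numbered 2 when any library other than control library 4 was left out, and those that fell numbered 5 without control library 4 and 1 without co-culture library 2 or 3 or control library 5. Of 10 Notch genes, 3 rose, 2 fell and 5 did not pass (4 and 2 adjusted over the list alone; camera adjusted p = 0.48). The ligand Dll1 rose by 1.503 ± 0.27 and the receptor Notch3 by 0.62 ± 0.105, whereas the target gene Hes1 fell by 2.96 ± 0.17 and the receptor Notch4 by 1.36 ± 0.14. The Notch median was 0.12 and the mean -0.12, with an upward sign from camera and a downward sign from fry and from camera on log2(TPM + 1).

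**Figure D3:**
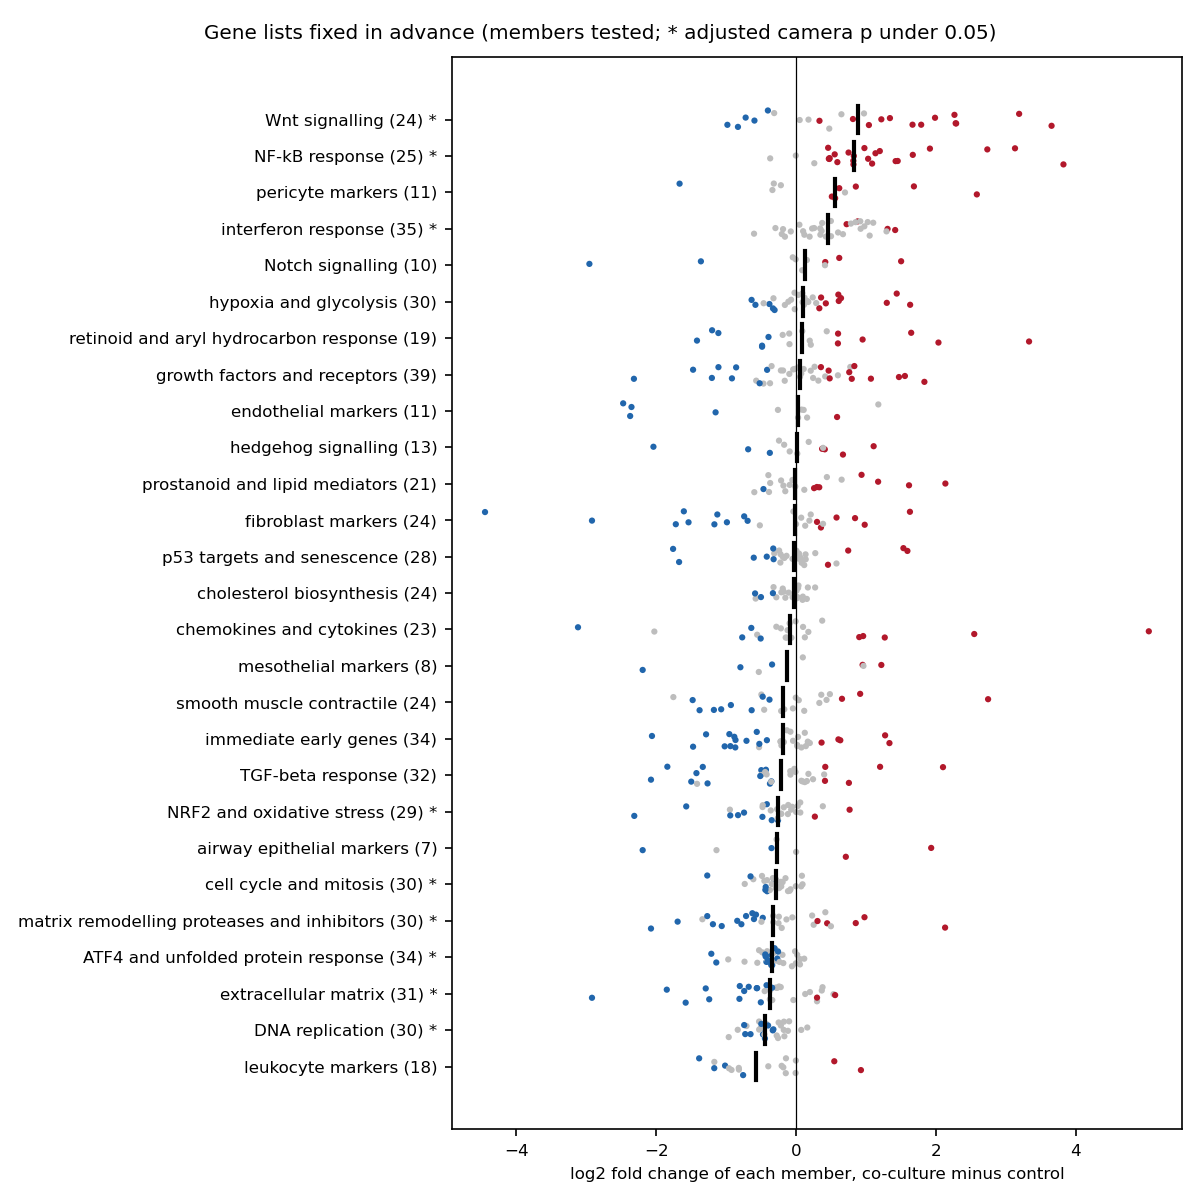
Log2 fold changes (co-culture minus control) of the members of each gene list fixed in advance, 1 point per tested member with the list's median. The NF-kB and Wnt lists had positive medians of 0.83 and 0.89, and the DNA replication and extracellular matrix lists had negative medians of -0.44 and -0.37; a star marks a camera adjusted p under 0.05.

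Most of the ATF4 and NRF2 genes that passed fell. Of 34 ATF4 and unfolded protein response genes, 14 fell and 20 did not pass (18 lower adjusted over the list alone; median -0.35, camera adjusted p = 1.63e-05). The ATF4 list gave adjusted p = 0.317 with an estimated correlation and values from 1.36e-06 to 0.00228 under its other alternatives. The mitochondrial folate enzyme Mthfd2 fell by 1.21 ± 0.099 and the pseudokinase Trib3 by 1.14 ± 0.14. Leaving out control library 4 gave 22 ATF4 members that fell, and 4, 5, 4, 6 and 6 fell without co-culture libraries 1 to 3 and control libraries 5 and 6. Of 29 NRF2 and oxidative stress genes, 2 rose, 9 fell and 18 did not pass (3 and 10 adjusted over the list alone; median -0.26, camera adjusted p = 0.00683). The NRF2 list gave adjusted p = 0.317 with an estimated correlation and values from 0.00213 to 0.0331 under its other alternatives. Its median was -0.105 without control library 4, where 5 members rose and 12 fell. NRF2 members that rose numbered 0 without each co-culture library or control library 6 and 1 without control library 5, and those that fell numbered 5 and 4 without co-culture libraries 2 and 3. Gpx3, a secreted glutathione peroxidase, fell from 1057 ± 84.9 to 356 ± 20.3 CPM and heme oxygenase 1 (Hmox1) fell by 0.74 ± 0.066. The transporter Abcc1 rose by 0.27 and the extracellular superoxide dismutase Sod3 by 0.77, and both calls were lost without co-culture library 1, 2 or 3 or control library 6 (edgeR adjusted p = 0.083, 0.148, 0.145 and 0.112 for Abcc1 and 0.0961, 0.0509, 0.113 and 0.0607 for Sod3), that of Abcc1 also without control library 5 (0.0553). Over all alternatives the adjusted p ran from 0.00757 to 0.398 for Abcc1 and from 0.00359 to 0.132 for Sod3. Immediate early genes missed the threshold (34 members, 5 rose, 13 fell and 16 did not pass; 5 and 14 adjusted over the list alone; median -0.19, camera adjusted p = 0.0637) but passed without control library 4 (0.0168) and without co-culture library 1, 2 or 3 (0.0408, 0.0177 and 0.0352), and with fry (0.0411), with values from 0.0167 to 0.197 over the alternatives other than the estimated correlation, where adjusted p = 0.6735, and 3 members rose without co-culture library 1 or 2. Egr1 and Egr2, zinc-finger transcription factors, fell by 1.29 ± 0.14 and 2.06 ± 0.21, while Fosl2, an AP-1 subunit, rose by 1.34 ± 0.104 and Ier3 by 1.27 ± 0.12. Hypoxia and glycolysis genes missed it as well (30 members, 9 rose, 5 fell and 16 did not pass; 10 and 5 adjusted over the list alone; median 0.104, camera adjusted p = 0.0685), and passed without co-culture library 1 (0.0408), with log2(TPM + 1) (0.0329) and with fry (0.0197; 0.0197 to 0.131 over those alternatives), with adjusted p = 0.646 with an estimated correlation. Hypoxia members that rose numbered 14 without control library 4 and 5 without co-culture library 3, and those that fell numbered 2 without each co-culture library or control library 6 and 3 without control library 5. Ndrg1 rose by 1.63 ± 0.106 and the pyruvate dehydrogenase kinase Pdk1 by 1.298 ± 0.103, while the oxidoreductase Ero1l fell by 0.58 and the glucose transporter Slc2a1 by 0.38.

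The remaining response lists did not pass by camera, but the retinoid and prostanoid lists passed upward with fry. Of 19 retinoid and aryl hydrocarbon genes, 6 rose, 6 fell and 7 did not pass (7 and 6 adjusted over the list alone; median 0.09, camera adjusted p = 0.48). The list gave adjusted p = 0.0035 with fry (0.0035 to 0.71 over its alternatives other than the estimated correlation, where adjusted p = 0.6735), and 3 members fell without co-culture library 2 or 3. With Ahr rose Ahrr, its repressor, by 2.04 ± 0.22 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00153), whereas the retinoic acid receptor Rarb and the retinal reductase Dhrs3 fell by 1.42 ± 0.18 and 1.11 ± 0.13. Of 21 prostanoid and lipid mediator genes, 7 rose, 1 fell and 13 did not pass (8 and 1 adjusted over the list alone). Their median was -0.01 and their mean 0.24, with an upward test (camera adjusted p = 0.22), and the median turned positive without control library 4 (0.05), co-culture library 3 (0.03) and control library 6 (0.002). The prostanoid list gave adjusted p = 8.75e-04 with fry (8.75e-04 to 0.456 over its alternatives other than the estimated correlation, where adjusted p = 0.639). Its members that rose numbered 3, 4 and 3 without co-culture libraries 1, 2 and 3 and 4 and 3 without control libraries 5 and 6, and 3 fell without control library 4. Enpp2, which makes lysophosphatidic acid, rose from 19.4 ± 0.822 to 85.5 ± 4.93 CPM, the sphingosine-1-phosphate receptor S1pr1 rose by 1.62, and the prostaglandin F receptor Ptgfr fell by 0.47. Of 28 p53 and senescence genes, 4 rose, 6 fell and 18 did not pass (6 and 9 adjusted over the list alone; median -0.02, camera adjusted p = 0.76), and the median was 0.03 without control library 4, where 7 rose and 10 fell, and 0.167 with log2(TPM + 1). The cyclin-dependent kinase inhibitors Cdkn2b and Cdkn1c rose by 1.54 ± 0.11 and 0.75 ± 0.091, and the p53 targets Gadd45a and Perp fell by 1.76 ± 0.12 and 1.67 ± 0.18. Of 24 cholesterol biosynthesis genes, 0 rose, 3 fell and 21 did not pass (3 lower adjusted over the list alone; median -0.04, camera adjusted p = 0.48), with Insig1, a sterol sensor partner, down by 0.50 ± 0.075 and the sterol desaturase Sc5d down by 0.59 ± 0.105. The Sc5d call was lost without co-culture library 2 or 3 (edgeR adjusted p = 0.0544 and 0.0579; 4.70e-05 to 0.363 over all alternatives), and 3 cholesterol members rose and 5 fell without control library 4, while 1 fell without co-culture library 2 or 3.

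Markers of other cell types were low or moved both ways, but fibroblast markers were not low. They summed to 8309 ± 431.5 CPM in co-culture and 11970 ± 930 CPM in controls. The contractile list summed to 4121 ± 144.4 and 4335 ± 200.3 CPM. Acta2, at 60.3 and 136 CPM, and Tagln, at 13.1 and 36.5 CPM, were a small part of it. These sums do not measure shares of cells, and the identity of the cells rests on the labels. Epcam, an epithelial adhesion molecule, was at 0.25 ± 0.0368 CPM in co-culture and 0.334 ± 0.331 CPM in controls and was too low to test. Of 26 airway epithelial markers measured, 7 could be tested, and 2 rose, 2 fell and 3 did not pass (2 and 2 adjusted over the list alone; median -0.28, camera adjusted p = 0.591). The epithelial list passed downward with fry (adjusted p = 0.0268; 0.0268 to 0.875 over its alternatives other than the estimated correlation, where adjusted p = 0.765), and 1 member rose and 1 fell when any co-culture library or control library 5 was left out. The basal cell factor Trp63 rose from 0.825 ± 0.186 to 3.196 ± 0.107 CPM and the keratin Krt18 fell from 20.8 ± 4.39 to 4.54 ± 0.369 CPM. Muc1 rose by 0.71 and the tubulin Tubb4b fell by 0.35, and both calls were lost without co-culture library 1, 2 or 3 or control library 5 (edgeR adjusted p = 0.0883, 0.117, 0.0939 and 0.0865 for Muc1 and 0.0806, 0.0877, 0.0975 and 0.0631 for Tubb4b). Over all alternatives the adjusted p ran from 0.0199 to 0.17 for Muc1 and from 0.00115 to 0.767 for Tubb4b. The epithelial list summed to 172 ± 1.17 CPM in co-culture and 225 ± 20.1 CPM in controls. Of 18 leukocyte markers, 2 rose, 4 fell and 12 did not pass (2 and 8 adjusted over the list alone; median -0.58). The leukocyte list missed the threshold (camera adjusted p = 0.0503) and passed it in 11 of its 14 alternatives other than the estimated correlation, with values from 3.73e-04 to 0.0821, and gave adjusted p = 0.56 with an estimated correlation. It passed in all with a library left out (0.0143, 0.0323 and 0.0236 without co-culture libraries 1 to 3, 0.0407 without control library 4 and 0.0138 without control library 5) except that without control library 6 (0.0691). Leukocyte members that fell numbered 8 without control library 4, and 1 rose when any co-culture library or control library 5 was left out. The scavenger receptor Marco rose by 0.93 ± 0.13 and the macrophage receptor Csf1r fell by 1.39 ± 0.21, as did C1qb by 1.02 ± 0.11. Of 11 endothelial markers, 1 rose, 4 fell and 6 did not pass (2 and 5 adjusted over the list alone), and the median of 0.03 and mean of -0.59 differed in sign (camera adjusted p = 0.369), with negative medians without co-culture library 1, 2 or 3 (-0.225, -0.02 and -0.10) or control library 4 (-0.02, where 2 rose). The endothelial list passed downward with fry (adjusted p = 0.0414) and log2(TPM + 1) (0.0229; 0.0229 to 0.517 over its alternatives other than the estimated correlation, where adjusted p = 0.689). Lyve1 fell by 2.47 ± 0.27, Esm1 fell by 2.37 ± 0.31, and the peptide Apln rose by 0.59. Of 24 fibroblast markers, 6 rose, 10 fell and 8 did not pass (6 and 10 adjusted over the list alone; median -0.02, camera adjusted p = 0.41), among them the dipeptidase Dpep1, down from 258 ± 6.17 to 88.8 ± 1.19 CPM, and the guidance factor Slit2, up from 155 ± 18.7 to 480.4 ± 26.2 CPM. The fibroblast median turned to 0.10 without control library 4, where 10 rose, against 3 without each co-culture library. The fibroblast list passed downward with fry (adjusted p = 0.00277) and log2(TPM + 1) (0.0109; 0.00277 to 0.605 over its alternatives other than the estimated correlation, where adjusted p = 0.646). Of 8 mesothelial markers, 2 rose, 3 fell and 3 did not pass (2 and 3 adjusted over the list alone; median -0.12, camera adjusted p = 0.599), with Aldh1a2 up by 0.95 and carboxypeptidase E (Cpe) down by 0.796, and the median was 0.07 without control library 4. Of 11 pericyte markers, 6 rose, 1 fell and 4 did not pass (6 and 1 adjusted over the list alone; median 0.56, camera adjusted p = 0.0947), with Tbx3 up by 0.86 ± 0.076 and Rgs5 down by 1.67 ± 0.17. Pericyte members that rose numbered 2, 3 and 2 without co-culture libraries 1, 2 and 3 and 3 without control library 5, and 3 fell without control library 4.

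Of 33858 transcripts tested, 326 rose and 319 fell (edgeR's quasi-likelihood test, Benjamini-Hochberg adjustment), from 569 genes, of which 499 were also called as genes. DESeq2's Wald test called 1095 transcripts higher and 1108 lower, beside 1090 and 1102 genes. Other alternatives with all libraries gave from 106 and 44 transcripts with log2(TPM + 0.1) to 518 and 528 with the stricter filter. Leaving out control library 4, 416 transcripts rose and 522 fell. Counts were 55 and 40, 53 and 36, and 37 and 33 without co-culture libraries 1, 2 and 3, 48 and 35 without control library 5, and 83 and 60 without control library 6. Isoform use changed in 29 of 7671 genes with several transcripts, 4 of them also called as genes, and 243 genes were at an unadjusted p under 0.05. Isoform use changed in 92 genes with the stricter filter and in 10 without co-culture library 1. The smallest adjusted p belonged to Tcf12, an E-box transcription factor (edgeR's diffSpliceDGE, Benjamini-Hochberg adjusted p = 5.07e-09): transcript NM_001253863 was at 30.7 ± 18.3 CPM in co-culture and 1.65 ± 2.85 CPM in controls, whereas XM_006510997 was listed at 0 in co-culture and was at 39.3 ± 19.5 CPM in controls. In Ltbp1, which binds latent TGF-beta, XM_006524350 was at 23.6 ± 2.78 CPM in co-culture and 2.06 ± 3.57 CPM in controls, and XM_006524349 was listed at 0 in co-culture and at 27.6 ± 6.21 CPM in controls. Aldh1a1, a retinaldehyde dehydrogenase, shifted toward NM_013467, at 42.6 ± 7.25 CPM in co-culture and 13.99 ± 3.77 CPM in controls (diffSpliceDGE adjusted p = 0.00118). In Dok4, an adaptor protein, XM_030243242 was at 5.39 ± 1.02 CPM in co-culture and listed at 0 in controls, and in Pcmt1, a protein repair methyltransferase, a transcript copy listed at 0 in co-culture was at 6.42 ± 4.02 CPM in controls. Transcripts listed at 0 throughout a group beside a close sibling that is not may reflect how reads were divided among them, and no fold is given.

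**Figure D4:**
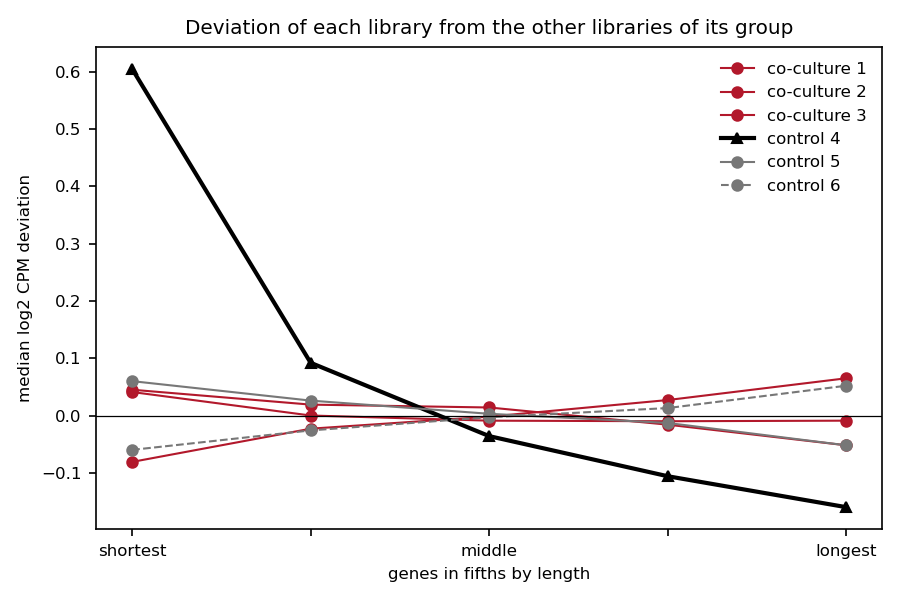
Median log2 CPM deviation of each library from the other libraries of its group (control libraries 5 and 6 against each other) for genes in 5 equal bins by length. Control library 4 went from 0.605 in the shortest genes to -0.16 in the longest, while the difference between these ends was at most 0.146 in size in the other libraries.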

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

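The length correction, the quality weights, the list tests on FPKM and TPM and the FPKM and TPM computed from counts were added after seeing the data. The alternatives on deposited FPKM and TPM were not run, because 12 deposited columns of control values were not used here. No paired analysis was possible because the columns of the control libraries are numbered 4 to 6 and share no number with the co-culture columns, so the alternatives with a replicate block were not run. The cause of the changes below was not tested unless it is named. Counts of genes (higher, lower) were 342 and 323 with a 2-fold minimum, which calls fewer by construction, 654 lower with log2(FPKM + 1) and 663 lower with log2(FPKM + 0.1), 512 and 238 with log2(TPM + 1), 469 and 232 with log2(TPM + 0.1), and 2201 and 2488 with quality weights. Transcripts numbered 1095 and 1108 with DESeq2, 205 and 200 with no filter, 518 and 528 with the stricter filter, which tests fewer transcripts, 201 and 163 with a 2-fold minimum, 194 lower with log2(FPKM + 0.1), 136 and 61 with log2(TPM + 1), and 106 and 44 with log2(TPM + 0.1). Isoform use changed in 92 genes with the stricter filter. Lists past the threshold numbered 9, and 15 with log2(TPM + 1), 0 with an estimated correlation and 16 with fry. With each library left out in turn, 612 to 2445 genes were higher and 598 to 2598 lower, 37 to 416 transcripts were higher and 33 to 522 lower, isoform use changed in 10 to 33 genes and 8 to 12 lists passed; the highest gene and transcript counts came without control library 4. Mki67 changed sign with log2(TPM + 1) (0.064), log2(TPM + 0.1) (0.067) and without co-culture library 1 (0.000, against -0.176 without another library). The p53 list (median 0.167) and the Notch list (median 0.209) changed direction with log2(TPM + 1), and fry gave the smooth muscle contractile list (median -0.191) and the Notch list (median 0.122) the other sign than camera. Of 111 named genes tested, 107 were called, 71 of them under all alternatives, 20 were lost only with TPM and 16 under another alternative, 15 of these with a library left out, which leaves fewer samples. Among list results, 349 kept their direction and side of the threshold, 15 were lost, 37 were gained and 4 changed sign. Of the genes called with all libraries, 0 changed sign under an alternative. At the depth found, with 3 libraries per group, simulated 2-fold changes were recovered in 91.04% of genes and 1.5-fold changes in 34.3%. For transcripts, 2-fold changes were recovered in 13.6%. Low-count genes and transcripts were not among those changed, so these shares do not cover them. Depth was not varied, so its part was not separated from that of replicate number and dispersion.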

Other observations

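The gene families, whose members were looked up after several had been noticed among the called genes, were chosen after the results were seen, as were the length correction, the computed FPKM and TPM, the other splits and the tests of the position of control library 4 and of carried-over cells. Leaving out a library, DESeq2's size factors and the estimated correlation had been fixed beforehand, and their use to weigh an explanation was decided after the results were seen. Complement genes went both ways. Of 13 tested, 7 rose: besides C3 and Cfb these were the C1 proteases C1s1 (from 244 ± 13.3 to 622 ± 3.64 CPM, n = 3 per group) and C1ra (1.37 ± 0.086, log2 ± SE), C2, C4b and the C1 inhibitor Serping1 (1.02 ± 0.055). The 3 chains of C1q (C1qa, C1qb and C1qc), which macrophages make, fell, as did Masp1 (-0.56). All 5 tested Serpina3 genes rose, with Serpina3n going from 347 ± 31.7 to 1513 ± 111 CPM, although these paralogs may share reads on chromosome 12. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment these calls were made with all libraries, and 0 called members changed sign with DESeq2's size factors, FPKM, TPM, the length correction or without control library 4, where C1ra was at 1.298. With TPM the calls of C1qb, C1qc, C4b and Masp1 were lost (limma adjusted p = 0.124, 0.273, 0.105 and 0.558). The paralogs may be hard to tell apart for the aligner, which was not tested.

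In other families most called members fell. Of 6 type IV collagen genes, which encode the basement membrane network, 5 fell, led by Col4a1 (from 2566 ± 317 to 1048 ± 45.9 CPM) and Col4a2 (from 1399 ± 204 to 591 ± 24.3 CPM), and Col4a3, at 0.696 and 1.31 CPM, did not pass. Fmo1, Fmo2 and Fmo4, flavin-containing monooxygenases on chromosome 1, fell, with Fmo2 going from 1008 ± 38.97 to 191 ± 21.7 CPM, while Fmo5 on chromosome 3 rose by 0.52. Among 6 IGF-binding proteins, Igfbp4 rose from 160.3 ± 28.5 to 472 ± 54.3 CPM, Igfbp3, Igfbp5, Igfbp6 and Igfbp7 fell, and Igfbp2 did not pass. Under the same 5 alternatives 0 called members of these families changed sign, but calls were lost: Igfbp6 with the length correction (edgeR adjusted p = 0.128), FPKM (limma adjusted p = 0.121) and TPM (0.788), Col4a4 with FPKM (0.148) and TPM (0.523), and Igfbp3 and Fmo5 with TPM (0.156 and 0.251). Pdgfra, a fibroblast marker and PDGF receptor, was chosen after its value was seen. It was at 847 ± 57.8 CPM in co-culture and 732 ± 91.1 CPM in controls and did not pass. Acta2 was at 60.3 ± 16.6 and 136 ± 14.4 CPM. Of 24 fibroblast markers tested, 6 rose and 10 fell, so Pdgfra does not stand for that list.

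Control library 4 stood apart from control libraries 5 and 6. A dependence on gene length was there: its deviation differed by 0.765 on the log2 scale between the shortest and the longest of 5 equal bins (median lengths 939 and 5973 bases, 11648 genes), against at most 0.146 in the other libraries. Length alone left much open, because the root mean square deviation from libraries 5 and 6 was 0.49 before and 0.33 after removing the length trend, against 0.137 between libraries 5 and 6. A mislabelled co-culture sample was excluded, since over 744 genes that separate the groups without library 4 its position was 0.032 on a scale from 0 (controls 5 and 6) to 1 (co-culture), where the co-culture libraries lay between 0.975 and 1.044. A candidate explanation is a difference in RNA quality or library preparation, for which no label gives a value, and a biological difference of that culture stays open as untested.

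The rise of NF-kB and Wnt list members (35 of 49 tested) was set against carried-over cells. The epithelial markers left little room for epithelial RNA as the source. The 20 of them under 1 CPM in controls summed to 2.86 CPM there and 5.29 CPM in co-culture, where Trp63 reached 3.196 CPM. Their difference of 2.43 CPM (SE 0.442) stood against a rise of 2593 CPM in the summed NF-kB and Wnt members. It was not excluded, because no sample shows how much of these RNAs epithelial cells carry, and only 26 of 40 listed epithelial markers were measured. The leukocyte markers differed by -47.2 CPM (SE 20.8), lower in co-culture, which argues against leukocyte RNA as the source. Control library 4 was not the source, since the members' median was 0.802 without it and 0.826 with it. Without that library 36 members were called higher. Signals passing from the epithelial cells through the membrane may account for the rise, as the design changes their presence, but no sample separates them from other effects of a shared plate. That hypothesis was drawn from these data and was not tested.

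Members of the cell cycle and DNA replication lists were lower in co-culture (16 of 60 called lower, 0 higher), although the series set out from a proliferation phenotype. Control library 4 was not the whole source: the median was -0.23 without it, against -0.33 with it, so it set part of the size. Gene length was not the whole source either, with a median of -0.282 after the length correction. Members called lower numbered 28 without library 4 and 22 after the length correction. These counts cannot decide, because calls among all genes rose as well, from 2663 to 5043 and 3615. Variation between cultures that all members share cannot be told apart from the treatment with 3 libraries a group. Both lists lost their call with an estimated correlation (largest adjusted p = 0.646, camera), but 0 lists passed under that setting. Even the NRF2 list, whose estimated correlation of 0.010 equals the preset, gave a camera adjusted p of 0.317. The loss therefore cannot decide the question. Shared variation stays as open for the NF-kB and Wnt lists (camera adjusted p = 0.317 and 0.442). A lower share of dividing cells on the fifth day may be one reading, for example if cells in co-culture had reached confluence earlier, but no cell number is given in the sources used here.

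The 10 possible splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 2663 called genes, 645 called transcripts, 29 genes with changed isoform use and 9 gene lists, against at most 0, 0, 20 and 9 in another split. For genes, transcripts and isoform use 1 split, the real one, gave a number as large, and for lists 2 splits did, the other being co-culture library 1 with control libraries 4 and 5.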
